A study of Mus musculus with 12 samples.

How the data were processed

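RNA-seq was measured in 12 libraries of mouse cell lines derived from embryonic fibroblasts (MEF). HP1γ, encoded by Cbx3, is a heterochromatin protein that binds methylated histone H3. Per the labels, 1 line lacks HP1γ and the other was given HP1γ back (HPg). Each line was grown untreated or with 100 nM phorbol 12-myristate 13-acetate (PMA), a phorbol ester that activates protein kinase C, dissolved in DMSO for 30 min. This gives 4 groups of 3 libraries, which the series' design text calls biological triplicates. The vehicle of the untreated cells is not given in the sources used here. One line stands for each genotype, so p-values measure the spread between cultures of these lines, and line and genotype cannot be told apart.

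Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into directional libraries, which were sequenced as paired ends. The deposited table holds raw read counts per gene, whole numbers that the authors did not normalize, as its values show. Per the submitters' processing notes, the tools were cutadapt 1.11, STAR 2.5.0a, featureCounts 1.4.6-p3 and Subread, with genome build mm9. The annotation release, the strand setting and whether reads or fragments were counted are not given in the sources used here. Genes that overlap a neighbour or an antisense partner, and members of families of near-identical copies, are therefore uncertain. No coordinates are printed, because the annotation used here (GENCODE M21, on GRCm38) is of another build. It served for symbols, chromosome, neighbouring genes, GC content, transcript length and gene span. Of 37310 genes in the table, 32620 had a symbol and 25029 had at least 1 count in some library.

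Total counts per library ranged from 111458145 to 159929347. How far this depth limited the comparisons was not tested. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of 104.1 to 689.2, so each library was counted as 1 replicate. Levels are given as CPM, the counts scaled to a common library total with TMM factors, as mean ± SD over 3 libraries. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total 15), which left 16630.

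Differences were tested with the edgeR quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3) with robust estimation and TMM factors. All 12 libraries entered one fit with a coefficient per group. The 5 comparisons were line without PMA, line with PMA, PMA in each line, and the interaction of line and PMA. P-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p below 0.05 are called changed. A permutation of 3 against 3 libraries cannot give p below 0.1.

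Lists of genes were tested with camera (limma 3.58.1), two-sided, with the preset correlation 0.01 and adjustment over the 31 lists of a comparison. Beside each are given the members called over all genes and those called when adjusted over the list alone. The lists were HP1 proteins and heterochromatin factors, immediate-early transcription factors, immediate-early signalling and feedback genes, NF-kB targets, interferon-stimulated and antigen presentation genes, splicing factors, extracellular matrix, G1/S and G2/M genes, cell cycle inhibitors and p53 targets, imprinted, germline, heat shock and unfolded protein response genes, long noncoding RNAs, genes with very long introns, protocadherins, Hox genes, Zfp genes, replication-dependent histones, ribosomal proteins, mitochondrially encoded genes, small nucleolar RNAs and olfactory and vomeronasal receptors. Markers of other cell types were muscle, adipocyte, cartilage and bone, epithelial, endothelial, blood and immune, neural and fibroblast lists. Median, mean and test direction differed in sign in 29 of the 155 list tests, none of which was called.

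The groups, the main test, the lists, the rule for named genes and the alternatives not described as added were fixed before the data were examined. The rule named Cbx3 first. Per comparison it took the 10 called genes with the largest increase and the 10 with the largest decrease, with a mean of at least 1 CPM in the higher group, no overlap between the libraries of the groups and a symbol that is not a predicted-gene or clone name. Up to 4 members per list were named in order of unadjusted p, and immediate-early and HP1 list members without that limit. Other genes were chosen after their values were seen, and the text says so.

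Libraries share replicate numbers across groups, and the numbers pair the samples. Deviations from the group means correlated at 0.159 to 0.558 in all 18 pairs with the same number, and at -0.517 to 0.163 in the 36 pairs with different numbers. The pairing comes from these data and from numbers in the labels, which do not say what a number shares. The fit with the number as a block is given where it changes the call of a list or of a named gene, or moves a count given in the text by over 1.5 times.

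Alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma-voom, fits of only the groups compared, the replicate block, removal of genes over 1 percent of the counts, stricter thresholds, an estimated correlation in camera, and leaving out each library in turn. A comparison of 2 groups was refitted only without each of its own 6 libraries. Added after seeing the data were a correction for GC content and transcript length (a spline with 5 degrees of freedom for each, over the 94.8% of tested genes that have both), removal of chromosome medians, each with and without the block, the first of these also with the block and another spline on gene span, leaving out the 4 libraries numbered 2, and the block without HPg library 2.

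The procedures were tested on simulated counts for the untreated line comparison over 16630 genes, 200 of them changed. The main test recovered 39% of the 2-fold and 79% of the 4-fold changes, with 4 false calls among 122. The blocked test recovered 69% and 86%, with 16 false calls among 171. A simulated shift of 0.5 in the list of immediate-early transcription factors gave adjusted p = 2.91e-28 and called 0 of the 30 other lists. Genes were drawn independently there, unlike in the data. It therefore does not test false list calls that come from correlation between genes.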

Results

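Total RNA was sequenced from MEF-derived mouse cells labelled as lacking HP1γ (knockout, KO) or as expressing it again (HPg), untreated or after 30 min of PMA. The design asks how the transcriptome depends on HP1γ under normal growth and under PMA. Total counts per library ranged from 111458145 (KO library 1) to 159929347 (HPg PMA library 2). The noncoding RNAs Rpph1, Rn7sk and Rmrp together took 8.59% to 19.25% of the counts of a library. HPg library 2 detected 17822 genes, against 19759 to 20656 in the other libraries.

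Cbx3 (ENSMUSG00000029836), the gene that encodes HP1γ, did not pass the test between the libraries labelled knockout and HPg. It had 38.7 ± 2.45 CPM in HPg and 36.5 ± 2.2 CPM in KO cells without PMA, and 38.6 ± 4.66 and 31.8 ± 4.37 CPM with PMA (SD, n = 3 each). Its counts per library ranged from 3564 to 6665. The log2 fold change of the libraries labelled knockout against HPg was -0.08 without PMA (adjusted p = 0.84, and 0.704 in the blocked fit) and -0.28 with PMA (adjusted p = 0.27, and 0.0876 in the blocked fit). With PMA the knockout-labelled library had less in all 3 pairs with the same replicate number (33.27 against 43.11, 26.85 against 33.8 and 35.2 against 38.93 CPM), and without PMA in 2 of 3. The direction without PMA reversed when chromosome medians were removed. Counts over a whole gene do not show which part of the transcript is present. The gene therefore does not check the genotype labels, and the groups are called knockout-labelled in the text that follows.

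Without PMA, Cttnbp2, Lrrc4c and Cftr were lower and Hapln1 and Rspo1 higher in knockout-labelled than in HPg cells. In the edgeR quasi-likelihood test Cttnbp2, a cortactin-binding protein of neurons, was lowest relative to HPg, with 0.188 ± 0.043 CPM against 4.57 ± 1.36 CPM (log2 fold change -4.59, SE 0.38, adjusted p = 9.72e-05). Lrrc4c, a netrin-G ligand, fell by 3.75 on the log2 scale (adjusted p = 1.4e-05) and Cftr, a chloride channel, was at 6.05 ± 0.887 CPM against 44.1 ± 5.03 CPM (-2.87, SE 0.22, adjusted p = 8.08e-05). Hapln1, a link protein of the hyaluronan matrix, was higher by 3.35 (SE 0.50, adjusted p = 0.0088), and so was Rspo1, a Wnt agonist, by 2.49 (SE 0.34, adjusted p = 0.00498). The desmosomal Dsp (2.75, adjusted p = 0.0345) and the imprinted noncoding RNA H19 (2.64, adjusted p = 0.0428) were higher as well.

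Among the other named genes, Hdac11, Rassf9, the phosphodiesterase Pde8b, Sgsm1, the ISWI remodeller Smarca1 and the growth-cone protein Gap43 were higher by 2.01 to 2.24. Dnaic1, the serotonin receptor Htr2c, the adhesion protein Cadm2, Fat2, the growth factor Bmp2, the Wnt receptor Fzd9 and Parm1 had log2 fold changes of -2.72 to -1.97. Of the 10 named higher genes, Rspo1, Pde8b, Sgsm1 and Gap43 stayed called in each fit that left out 1 library. Of the 10 named lower genes, all but Dnaic1, Fat2 and Fzd9 did. In total 134 genes were higher and 85 lower, 219 of 16630, and 2083 (1178 higher, 905 lower) in the blocked fit. DESeq2 called 775 and a fit of only these 2 groups 12, and with chromosome medians removed 105 were higher and 38 lower (868 and 296 with the block). The excess of higher genes did not hold with the correction for GC content and length, with 219 higher and 204 lower. With the block as well it turned to 1355 higher and 1564 lower, and to 1465 and 1748 with gene span added. Of the 16630, 3079 (18.51%) had no overlap between the libraries of the groups, where chance gives 10%. The count was 74, 329 and 49 without HPg library 1, 2 or 3, and 75, 125 and 46 without KO library 1, 2 or 3.

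The list of inflammatory genes was called higher in untreated knockout-labelled cells. The NF-kB list had 27 of 33 members above 0, a median of 0.41 and adjusted p = 2.32e-05, which was adjusted p = 0.549 with an estimated correlation. Tnfaip2 passed over all genes (1.07, adjusted p = 0.0176), and 9 members did when adjusted over the list alone, as in the blocked fit, among them the apoptosis inhibitor Birc3 (0.74) and the chemokine Cxcl5 (1.14), which the blocked fit called over all genes (adjusted p = 0.00103 and 0.00298). The interferon list was higher too, with a median of 0.68 (adjusted p = 0.00107, and adjusted p = 0.399 with an estimated correlation). Irf9 (0.80) and Parp14 (1.06) were higher and the RNA sensor Ifih1 was lower (-0.90), while adjusted over the list alone 8 members were higher and 1 lower, and 9 and 2 in the blocked fit. This call ended with a filter of 1 CPM (adjusted p = 0.0672).

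Protocadherin cluster genes, which encode neuronal adhesion proteins from tandem copies, lay above 0 in 20 of 22 members (median 0.57, adjusted p = 2.32e-05, and adjusted p = 0.605 with an estimated correlation). Pcdhb20 passed over all genes (0.90), 4 members did when adjusted over the list alone and 9 in the blocked fit. The extracellular matrix list was higher (median 0.32, adjusted p = 0.00263, and adjusted p = 0.688 with an estimated correlation). Its collagen Col11a1 (1.38) passed over all genes and 4 members when adjusted over the list alone, and 17 were higher and 3 lower in the blocked fit. The matrix call ended without HPg library 1 (adjusted p = 0.124), HPg library 3 (0.148) or KO library 2 (0.209).

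The 2 cell cycle lists were called lower, with small medians. Of the G1/S list, which holds replication genes such as Mcm2 and E2f1, 1 of 28 members lay above 0 (median -0.23, adjusted p = 2.32e-05, and adjusted p = 0.605 with an estimated correlation). The G2/M list, with Cdk1 and Cdc20, had a median of -0.21 (adjusted p = 0.00107, and adjusted p = 0.688 with an estimated correlation). No member of either list passed with the edgeR test, over all genes or adjusted over the list alone, and the blocked fit called 8 and 6 lower. The largest changes by unadjusted p were E2f1 (-0.52) and Cdk1 (-0.62). The G2/M call ended without HPg library 1 (adjusted p = 0.0906) or KO library 2 (0.0649).

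Several lists of tissue genes were called higher with less stability. For the epithelial list (Dsp passed, also adjusted over the list alone, and 3 members in the blocked fit) adjusted p was 0.0256, and adjusted p = 0.399 with an estimated correlation. It was not called without HPg library 1 (0.0744), HPg library 3 (0.0728) or KO library 1 (0.078). The neural list had 5 of 10 members above 0 and a median of 0.05, and of its members Gap43 and the adhesion protein Ncam1 (1.28) passed, also adjusted over the list alone (4 in the blocked fit). Its adjusted p was 0.0207, and adjusted p = 0.399 with an estimated correlation. It was not called without HPg library 1 (0.124), HPg library 3 (0.079) or KO library 2 (0.0666). Imprinted genes (H19 passed, also adjusted over the list alone, and 3 members in the blocked fit) had adjusted p = 0.0429, adjusted p = 0.605 with an estimated correlation and 0.0525 in the blocked fit. They were not called without HPg library 1 (0.31), HPg library 3 (0.148) or KO library 2 (0.211), with a filter of 1 CPM (0.0672), with the correction for GC content and length (0.0748), or with that, gene span and the block (0.0971).

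Germline genes had adjusted p = 0.0429, and adjusted p = 0.399 with an estimated correlation and 0.123 in the blocked fit. Of their 14 members none passed over all genes and Ddx4 (1.25) did when adjusted over the list alone and, over all genes, in the blocked fit (adjusted p = 0.00437). The call ended without HPg library 1 (0.0807), 2 (0.104) or 3 (0.0753), without KO library 1 (0.0506) or 3 (0.133) and without the libraries numbered 2 (0.064). It ended too with a filter of 1 CPM (0.0552), with the correction for GC content and length (0.0748, and 0.185 with gene span and the block) and with chromosome medians removed (0.0582). Zfp genes, zinc finger protein genes taken by their symbol and many with related copies, were higher as a list, with 237 of 317 members above 0 (median 0.14, adjusted p = 0.00128, and adjusted p = 0.605 with an estimated correlation). Zfp467, Zfp583 and Zfp105 were called higher and Zfp365 lower, also adjusted over the list alone, and 30 were higher and 1 lower in the blocked fit. This call ended without HPg library 1 (0.0863) or KO library 2 (0.0649). The list of replication-dependent histone genes was called lower (median -0.25, adjusted p = 0.0256, and adjusted p = 0.857 with an estimated correlation), although the variants Hist1h2aa (1.17) and Hist1h2ba (1.03) were called higher, also adjusted over the list alone. They were not called without HPg library 1 (0.733) or 3 (0.2), turned upward without KO library 2 (0.885), and lost the call with a filter of 1 CPM (0.0552) and with the correction for GC content and length (0.125, and 0.227 with gene span and the block).

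The 19 other lists were not called without PMA. The HP1 list, with Cbx1 (-0.06), Cbx5 (0.12) and the methyltransferases Suv39h1 (-0.16) and Suv39h2 (-0.38), had adjusted p = 0.602, and none of its 24 members passed, with 1 higher in the blocked fit. Adjusted p was 0.528 for immediate-early transcription factors (Egr3 higher, 1.93, and 2 higher and 1 lower in the blocked fit), 0.531 for immediate-early signalling genes (Zfp36l1 higher, Rcan1 lower, and 3 and 6 in the blocked fit), 0.339 for splicing factors, 0.343 for heat shock genes and 0.453 for cell cycle inhibitors and p53 targets. It was 0.339 for long noncoding RNAs, 0.336 for genes with very long introns, 0.453 for Hox genes, 0.203 for ribosomal proteins, 0.376 for mitochondrially encoded genes, 0.811 for small nucleolar RNAs and 0.336 for olfactory and vomeronasal receptors. For markers of other cell types it was 0.223 for muscle, 0.974 for adipocytes, 0.336 for cartilage and bone (Omd higher, and 4 higher and 1 lower in the blocked fit), 0.336 for endothelium (Erg higher, and 2 and 1 in the blocked fit), 0.335 for blood and immune cells and 0.615 for fibroblasts.

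**Figure D1:**
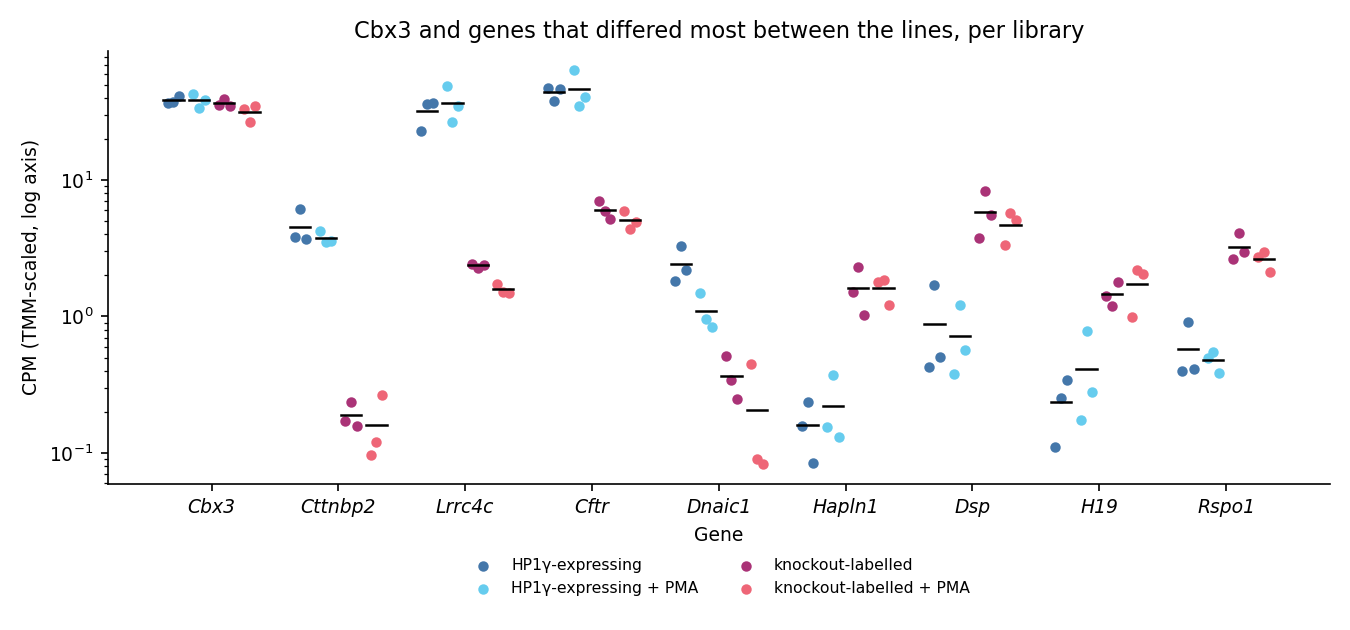
CPM per library on a log axis for Cbx3 and 8 genes named in the untreated comparison of the lines, with points for single libraries, colours for the 4 groups and black lines for group means. Cbx3 lies between 26.9 and 43.1 CPM in all 12 libraries, while Cttnbp2, Lrrc4c, Cftr and Dnaic1 lie lower, and Hapln1, Dsp, H19 and Rspo1 higher, in all knockout-labelled libraries than in the HPg libraries of the same treatment.

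With PMA, Cttnbp2, Lrrc4c and Cftr were again lower and Hapln1, Dsp and Rspo1 higher in knockout-labelled cells. Cttnbp2 (-4.56), Lrrc4c (-4.55, SE 0.25, adjusted p = 4.55e-06), Cadm2 (-3.36), Cftr (-3.19), Htr2c (-3.03) and Magi2 (-2.73), a synaptic scaffold, were lower in knockout-labelled cells, as were Elmod1 (-3.67), Dnaic1, Fat2 and Parm1. Hapln1 (2.86), Dsp, Rspo1 (2.46, SE 0.34, adjusted p = 0.00555), Ppfibp2 (2.44), Cytl1 and Smarca1 were higher. So were Qpct, the protease inhibitor Serpina3g (2.04), Ripk3, a kinase of necroptosis (2.02), and Vwf. Of the named genes, Rspo1, Ppfibp2 and Serpina3g, and Cttnbp2, Lrrc4c, Cadm2, Cftr, Htr2c and Parm1, stayed called in each fit that left out 1 library. Chd3, a chromatin remodeller chosen after its values were seen, was higher without PMA (1.89, adjusted p = 8.44e-06) and with it (1.88, adjusted p = 4.55e-06).

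In total 215 genes were higher and 196 lower with PMA, 411 in all, and 3090 (1578 higher, 1512 lower) in the blocked fit. DESeq2 called 1184, and with chromosome medians removed 148 were higher and 62 lower (1319 and 740 with the block). With the correction for GC content and length 300 were higher and 326 lower (1643 and 1842 with the block). The split was 163 higher and 217 lower when scaled by library size only, and 270 and 129 with upper-quartile factors. No overlap between groups was found for 4151 genes (24.96%), where chance gives 10%. The count was 70, 573 and 60 without HPg PMA library 1, 2 or 3, and 72, 136 and 161 without KO PMA library 1, 2 or 3.

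The 2 immediate-early lists and the NF-kB list were called higher in PMA-treated knockout-labelled cells than in PMA-treated HPg cells, and all 3 calls end with an estimated correlation. The NF-kB list had 32 of 33 members above 0 (median 0.69, adjusted p = 1.15e-10, and adjusted p = 0.291 with an estimated correlation). Tnfaip2 (1.25), Nfkbie (1.00) and Nfkb2 (0.69) passed over all genes, 16 members did when adjusted over the list alone and 17 in the blocked fit. Of immediate-early transcription factors, which respond to growth signals without new protein, 30 of 34 lay above 0 (median 0.50, adjusted p = 3.71e-08, and adjusted p = 0.447 with an estimated correlation). Fosl1 (0.63) and Egr3 passed, 7 did when adjusted over the list alone, and 19 in the blocked fit. Of the signalling and feedback genes 30 of 40 lay above 0 (median 0.41, adjusted p = 1.98e-05, and adjusted p = 0.447 with an estimated correlation). Zfp36l1 (0.84), Plk2 (0.47) and the growth factor Hbegf (0.87) passed. Adjusted over the list alone 11 members were higher and 1 lower, and 20 and 3 in the blocked fit.

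The extracellular matrix list (median 0.36, adjusted p = 0.00059, and adjusted p = 0.62 with an estimated correlation) was higher with PMA too, with Fbln2 (1.76) and Col11a1 (1.16) called over all genes and 4 members adjusted over the list alone. In the blocked fit 21 were higher and 2 lower. The epithelial list (adjusted p = 0.002, and adjusted p = 0.283 with an estimated correlation; Dsp called, 4 adjusted over the list alone, 5 in the blocked fit) and the protocadherins were higher. The latter had 20 of 22 members above 0 (adjusted p = 0.00059, and adjusted p = 0.62 with an estimated correlation), with Pcdhb20 called, also adjusted over the list alone, and 8 in the blocked fit. The neural list was called with Gap43 (6 of 10 above 0, median 0.56, adjusted p = 0.0428, and adjusted p = 0.447 with an estimated correlation), with 2 members adjusted over the list alone and 4 in the blocked fit. It was not called without HPg PMA library 1 (0.0996) or 3 (0.0572), or KO PMA library 2 (0.0595) or 3 (0.0785).

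G1/S genes (1 of 28 above 0, adjusted p = 0.00022) and G2/M genes (0 of 28 above 0, median -0.29, adjusted p = 4.05e-05) were again called lower as lists, both with adjusted p = 0.62 with an estimated correlation. The edgeR test called no member of either, also adjusted over the list alone, and the blocked fit called 10 and 6 lower, with E2f1 (-0.42) and the checkpoint kinase Bub1 (-0.68) among them. The list of genes with very long introns was called lower, with 4 of 20 above 0 (adjusted p = 0.0122, and adjusted p = 0.651 with an estimated correlation) and Magi2 called, also adjusted over the list alone, and 6 in the blocked fit. That call ended without HPg PMA library 2 (0.0959) or KO PMA library 1 (0.295), and in the blocked fit corrected for GC content, length and gene span (0.0849). The splicing factor list was called lower (median -0.13, adjusted p = 0.0281, and adjusted p = 0.62 with an estimated correlation) with no member called by edgeR, also adjusted over the list alone, and 4 in the blocked fit. Their call ended without HPg PMA library 1 (0.414) or KO PMA library 1 (0.0838) or 2 (0.0558), with a filter of 1 CPM (0.0989) and with the correction for GC content and length (0.318, and 0.186 with gene span and the block).

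The histone list was called higher with PMA (median 0.14, adjusted p = 0.0266, adjusted p = 0.711 with an estimated correlation, and 0.058 in the blocked fit). Hist1h2ba (1.65) and Hist1h2aa (1.72) passed, also adjusted over the list alone. The call ended without HPg PMA library 1 (0.111) or KO PMA library 1 (0.345), with the correction for GC content and length (0.497, and 0.952 with gene span and the block) and with the block and chromosome medians removed (0.0795). The 19 other lists were not called with PMA, with adjusted p from 0.0823 for the interferon list to 0.958 for small nucleolar RNAs.

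Whole chromosomes differed between the lines in both treatments. In the blocked fit the median log2 fold change over expressed protein-coding genes was -0.30 without and -0.29 with PMA on chromosome 10, -0.22 and -0.17 on chromosome 8, and 0.29 and 0.25 on chromosome 14. Chromosome 2 was at -0.17 and -0.19, chromosome 6 at -0.17 and -0.21 and chromosome 12 at 0.20 and 0.11. Of the 85 genes called lower without PMA, 22 lie on chromosome 10, as do 59 of the 196 called lower with PMA. Chromosome 14 holds 18 of the genes called higher without PMA and 29 of those with PMA, and 0 of the genes edgeR called lower in either. Cftr and Cttnbp2, both lower in knockout-labelled cells, are neighbours on chromosome 6 in GENCODE M21.

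**Figure D2:**
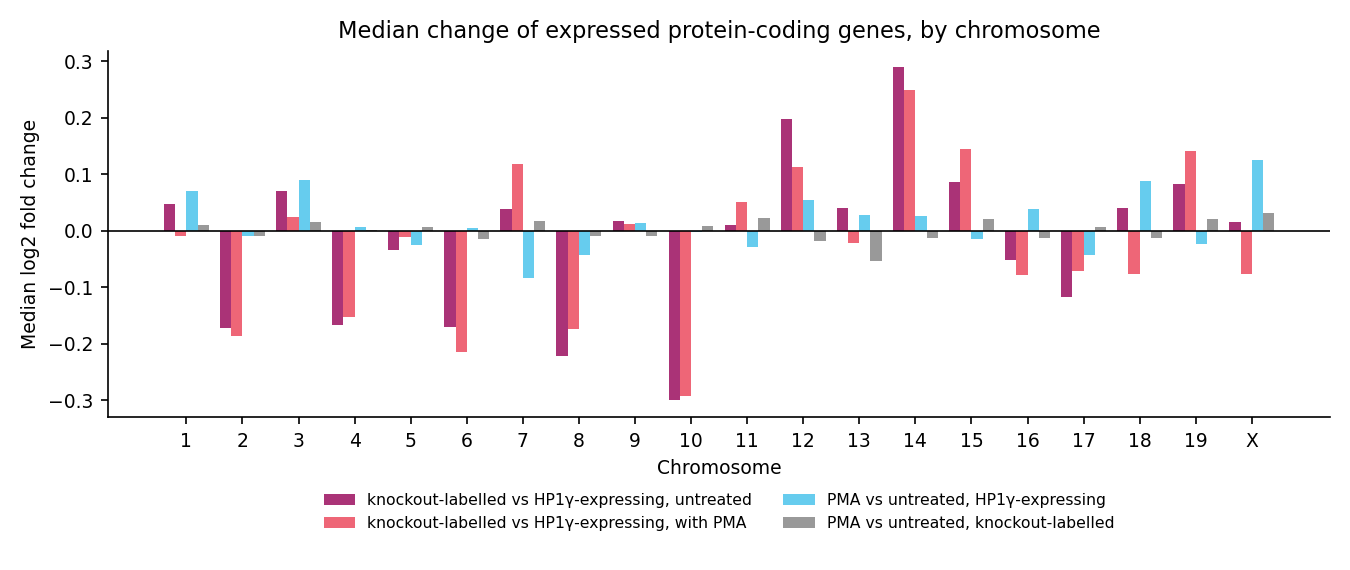
Median log2 fold change of expressed protein-coding genes per chromosome in the blocked fit, with bars for the 2 comparisons of the lines and the 2 comparisons of PMA. Bars of the lines reach -0.30 on chromosome 10 and 0.29 on chromosome 14, and both treatments give like values there.

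The line differences without and with PMA, which share no library, correlated across 16630 genes with Pearson r = 0.614 and Spearman rho = 0.563, where genes are not independent replicates. Called higher in both were 100 genes, against 1.73 for independent lists, and called lower in both were 58, against 1. Both sets of calls share one estimate of the spread from all 12 libraries, so these values are not a chance level. No gene was called in opposite directions by edgeR, and 1 was in the blocked fit.

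PMA switched on immediate-early genes in HPg cells. The zinc finger factor Egr3 rose from 0.0405 ± 0.0235 to 16.7 ± 4.75 CPM (log2 fold change 8.68, SE 0.35, adjusted p = 4.61e-08), Egr2 by 7.75, Egr4 by 6.87 and Egr1 by 5.45. Fos, a subunit of AP-1, rose from 2.1 ± 0.656 to 143 ± 40.3 CPM (6.10, SE 0.42, adjusted p = 6.89e-06). The nuclear receptors Nr4a3 (6.03) and Nr4a1 (5.96), the cytoskeletal Arc (4.94), the antiproliferative Btg2 (4.62) and the AP-1 subunit Junb (4.17) completed the 10 largest increases, and all stayed called in each fit that left out 1 library. Decreases were smaller. The zinc finger gene Zfp362 fell by 1.46 (SE 0.26, adjusted p = 0.00873) and alone of the 10 stayed called in each such fit. Lmtk3 fell by 1.38, and the odd-skipped factors Osr2 and Osr1 fell by 1.38 and 1.25. Npcd, which overlaps Nptxr and Cbx6, Zfp273, Nr6a1os, which is antisense to Nr6a1, Rasl11b, Zfp108 and Tspan32 had log2 fold changes of -1.77 to -1.21, and the overlapping and antisense genes are uncertain.

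In HPg cells 421 genes rose and 153 fell, 574 in all, of which 95 were not protein-coding, and the blocked fit called 2462 (1433 and 1029). DESeq2 called 1212 and a fit of only these 2 groups 222 (197 and 25). With upper-quartile factors the split was 316 and 193. No overlap between groups was found for 3774 genes (22.69%), where chance gives 10%. The count was 332, 321 and 244 without HPg library 1, 2 or 3, and 319, 268 and 251 without HPg PMA library 1, 2 or 3.

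Of 34 immediate-early transcription factors 25 rose over all genes and 28 when adjusted over the list alone, with a median of 1.58 (adjusted p = 6.47e-116, and adjusted p = 0.00118 with an estimated correlation). Fosl1 (3.47), Ier2 (3.53), Atf3 (2.40), Jun (1.30) and Myc (1.17) were among them, while Klf2 (-0.36), Jund (-0.25), Srf (-0.07) and Id3 (0.05) did not pass. Of 40 signalling and feedback genes 25 rose (median 1.4, adjusted p = 4.42e-65, and adjusted p = 0.00107 with an estimated correlation), and adjusted over the list alone 29 rose and 1 fell. They included the mRNA-decay factor Zfp36 (3.64), the EGF receptor ligands Hbegf (2.89) and Areg (3.31), the EGF receptor inhibitor Errfi1 (3.50) and the phosphatases Dusp6 (1.61), Dusp5 (1.67) and Dusp1 (1.14). Of 33 NF-kB targets 16 rose and 20 when adjusted over the list alone (median 0.78, adjusted p = 3.3e-23, adjusted p = 0.0421 with an estimated correlation and 0.108 with that and the block). Nfkbiz (2.89) and the chemokines Ccl20 (3.43), Ccl7 (3.43) and Ccl2 (3.07) led it.

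The list of splicing factors was called higher with a median of 0.31 and Hnrnpd (0.77), Tra2b (0.58) and Sf1 (0.44) called over all genes, 10 adjusted over the list alone and 17 in the blocked fit (adjusted p = 1.13e-07, and adjusted p = 0.349 with an estimated correlation). The list of heat shock and unfolded protein response genes was called higher, led by the stress factor Ddit3 (1.70) and the chaperone Dnajb1 (0.89), the 2 called also when adjusted over the list alone, and 5 were called in the blocked fit (adjusted p = 0.00271, and adjusted p = 0.646 with an estimated correlation). Their call ended without HPg library 3 (0.0591). Cell cycle inhibitors and p53 targets were called higher with Cdkn1a (1.51), Mdm2 (0.71) and Plk2 (0.65), and 4 adjusted over the list alone (adjusted p = 0.0386, and adjusted p = 0.203 with an estimated correlation), with a median of 0.08 that was -0.002 with upper-quartile factors. In the blocked fit 5 members were higher and 1 lower. The call ended without HPg library 2 (0.0717) or 3 (0.0873), HPg PMA library 3 (0.072) or the libraries numbered 2 (0.0938).

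The list of replication-dependent histone genes was called lower, with 3 of 54 above 0 and a median of -0.40 (adjusted p = 1.07e-06, and adjusted p = 0.952 with an estimated correlation). The edgeR test called none, also adjusted over the list alone, and the blocked fit 7. The PMA response of HPg cells correlated with GC content (rho = -0.478), where histone genes have a median GC content of 58.6% and splicing factors of 44.1%, against 49.8% for all tested genes. Both list calls stayed after the correction for GC content and length (adjusted p = 1.58e-06 and 3e-05). Of 317 Zfp genes 15 fell and 6 rose, and 30 and 13 when adjusted over the list alone (adjusted p = 0.0439, adjusted p = 0.965 with an estimated correlation and 0.0607 in the blocked fit, which called 49 and 18). The increases included Zfp36, which is an mRNA-binding protein, Zfp948 (1.47) and Zfp655 (1.10). This call ended without HPg library 2 (0.149) or 3 (0.0964), without HPg PMA library 2 (0.147) or 3 (0.171), without the libraries numbered 2 (0.47) and with chromosome medians removed (0.163). The 23 other lists had adjusted p from 0.1 for Hox genes to 0.954.

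**Figure D3:**
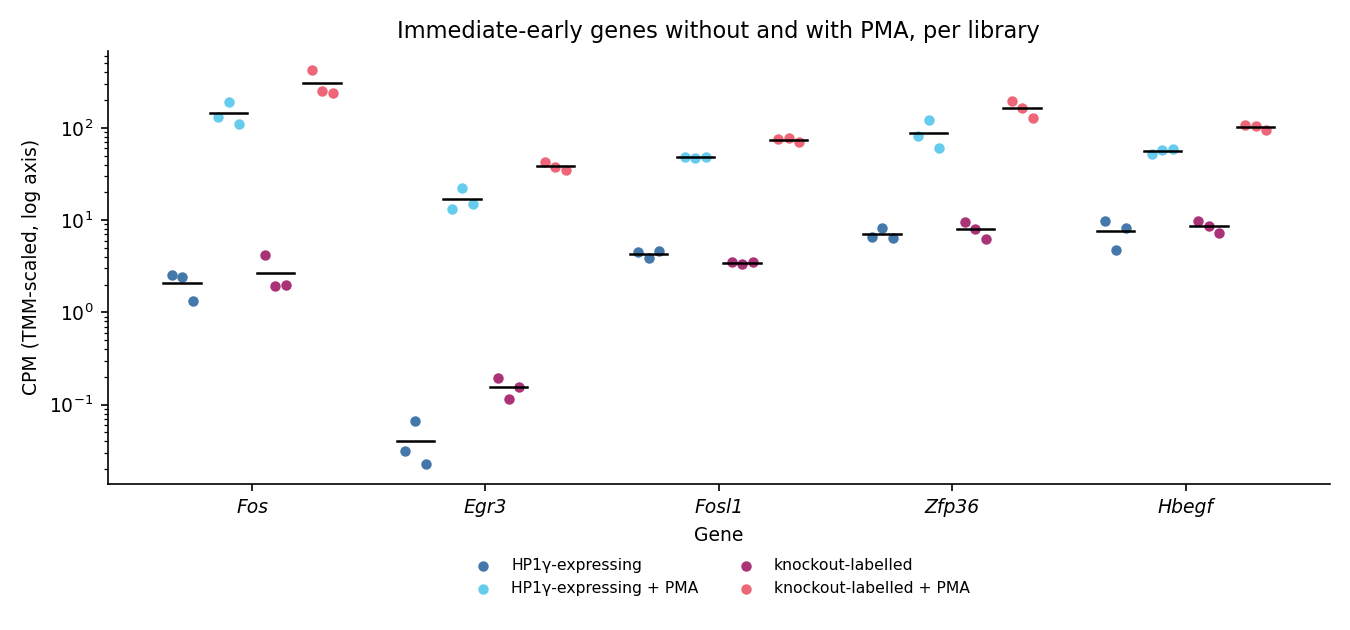
CPM per library on a log axis for Fos, Egr3, Fosl1, Zfp36 and Hbegf, with points for single libraries, colours for the 4 groups and black lines for group means. Each PMA library lies above each untreated library of its line, and mean Fosl1 is 48.0 CPM in HPg and 74.4 CPM in knockout-labelled cells with PMA.

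In knockout-labelled cells PMA raised the same 10 genes most. Egr2 rose by 8.16 (SE 0.53, adjusted p = 2.77e-06), Egr3 by 7.95, Egr4 by 6.55, Egr1 by 5.50 and Fos by 6.81, from 2.7 ± 1.29 to 302.2 ± 101 CPM. Nr4a1 (6.23), Nr4a3 (5.97), Arc (5.86), Btg2 (4.89) and Junb (4.54) followed, and all 10 stayed called in each fit that left out 1 library. Decreases were again smaller, and 3 of the 10 named are Zfp genes. Zfp273 fell by 1.89 (SE 0.27, adjusted p = 0.00153) and Zfp108 (-1.76) was lower, with Zfp457 at -1.86, the pseudophosphatase Styxl1 at -1.73 and Napb, a factor of vesicle fusion, at -1.59. Trav13-3 (-3.75) and Trav13-2 (-1.57), T cell receptor segments with near-identical copies, are uncertain, as is Npcd (-1.51), and Lca5l (-1.66) and Fign (-1.50) were lower too. Trav13-3 and Trav13-2 also fell in HPg cells (-3.55 and -1.97), where means below 1 CPM kept them from the named genes. Of the 10 named decreases, all but Zfp457, Lca5l and Npcd stayed called in each fit that left out 1 library.

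In these cells 468 genes rose and 271 fell, 739 in all, of which 149 were not protein-coding, and the blocked fit called 2221 (1130 and 1091). DESeq2 called 1279. Scaled by library size only the split was 307 and 424, and this scaling moved the median of all genes from -0.016 to -0.142. No overlap between groups was found for 3632 genes (21.84%), where chance gives 10%. The count was 482, 409 and 295 without KO library 1, 2 or 3, and 334 and 367 without KO PMA library 2 or 3.

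Of the immediate-early transcription factors 27 of 34 rose, also adjusted over the list alone (median 2.05, adjusted p = 4.87e-153, and adjusted p = 0.000367 with an estimated correlation). Fosl1 rose by 4.44 from 3.44 to 74.4 CPM, and Ier2 (4.10), Atf3 (3.14), Myc (1.79) and Jun (1.85) rose as well. Of signalling and feedback genes 28 of 40 rose and 30 when adjusted over the list alone (median 1.64, adjusted p = 1.13e-96, and adjusted p = 0.000206 with an estimated correlation), with Zfp36 (4.36), Areg (4.37), Errfi1 (4.08), Hbegf (3.57) and Ier3 (3.33). Of NF-kB targets 18 of 33 rose and 22 when adjusted over the list alone (adjusted p = 6.52e-33, adjusted p = 0.0119 with an estimated correlation and 0.0512 with that, the block and the correction for GC content and length), with Nfkbiz (3.48), Ccl20 (3.38), the interferon factor Irf1 (2.65) and Nfkbia (2.17). The list of cell cycle inhibitors and p53 targets was called higher (17 of 24 above 0), with Cdkn1a (1.89), Plk2 (0.99), Mdm2 (0.60) and Tgfb1 (1.24) called over all genes and 5 adjusted over the list alone (adjusted p = 0.000137, adjusted p = 0.0209 with an estimated correlation and 0.115 with that and the block). The blocked fit called 7.

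Heat shock genes had 24 of 25 members above 0 (median 0.31, adjusted p = 2.53e-07, and adjusted p = 0.216 with an estimated correlation), with Ddit3 (1.88), Dnajb1 (1.33), Chac1 (1.09) and Dnajb9 (0.53) called, 5 adjusted over the list alone and 10 in the blocked fit. The splicing factor list was called higher with a median of 0.24, with Sf1, Hnrnpd and Tra2b called over all genes, 4 adjusted over the list alone (adjusted p = 0.000137, and adjusted p = 0.531 with an estimated correlation), and the blocked fit had 12 higher and 1 lower. Of Zfp genes 38 fell and 6 rose, and 79 and 14 when adjusted over the list alone (median -0.24, adjusted p = 1.94e-08, and adjusted p = 0.229 with an estimated correlation). The blocked fit called 88 and 17. Genes with very long introns had 1 of 20 above 0 (median -0.43, adjusted p = 0.00708, and adjusted p = 0.962 with an estimated correlation), with none called by edgeR, also adjusted over the list alone, and 4 in the blocked fit. That call ended without KO library 2 (0.341) or KO PMA library 1 (0.299), and in the blocked fit corrected for GC content, length and gene span (0.836). The PMA response of these cells correlated with gene span (rho = -0.371), and so did the deviations of single libraries from their group, at -0.613 for KO library 1, 0.592 for KO library 2, -0.494 for KO PMA library 1 and 0.426 for KO PMA library 2. Ribosomal protein genes had 78 of 81 above 0 (median 0.25, adjusted p = 0.0113, and adjusted p = 0.977 with an estimated correlation) and none called, also adjusted over the list alone. They were not called without KO PMA library 1 (0.17) or 3 (0.132), without the libraries numbered 2 (0.0587) or in the blocked fit corrected for GC content, length and gene span (0.138), and turned downward without KO library 2 (0.788). The 22 other lists had adjusted p from 0.0536 for Hox genes to 0.962.

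The PMA responses of the lines, which share no library, correlated across genes with r = 0.638 and rho = 0.551. Called higher in both were 299 genes, against 11.8 for independent lists, and called lower in both were 88, against 2.49. Here too the calls share one estimate of the spread, so these values are not a chance level. No gene was called in opposite directions, by edgeR or in the blocked fit.

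Whether PMA acted differently in the lines was tested by the interaction, in which the immediate-early lists of signalling genes and transcription factors were called higher in knockout-labelled cells while no single gene passed in edgeR. Both list calls end with an estimated correlation (adjusted p = 0.245 and adjusted p = 0.391). The edgeR test called 0 of 16630 genes, with 328 at an unadjusted p below 0.05, and the blocked fit also called 0, with 1275. DESeq2 called 1, the AP-1 subunit Fosl1 (0.97, adjusted p = 5.19e-06), and limma-voom 0. In the edgeR test Fosl1 had 0.97 (SE 0.14, adjusted p = 0.27, and 0.0541 in the blocked fit), the blocked fit without HPg library 2 called it (1.04, adjusted p = 0.0413), and it was the one member that passed when adjusted over the list alone. Without KO library 1 edgeR called Gm6565 (7.37, adjusted p = 0.0201), a processed pseudogene.

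The signalling and feedback list had 36 of 40 members above 0 in the interaction (median 0.45, adjusted p = 2.04e-11, and adjusted p = 0.245 with an estimated correlation), with Ier3 (0.54), Phlda1 (0.56), Trib1 (0.79) and Hbegf (0.69) first by unadjusted p. The transcription factor list had 30 of 34 (median 0.34, adjusted p = 1.22e-09, and adjusted p = 0.391 with an estimated correlation), with Klf10 (0.68), Myc (0.63) and Jun (0.55) after Fosl1. Both calls held in each of 12 fits that left out 1 library. NF-kB targets (adjusted p = 0.00875) and heat shock genes (adjusted p = 0.00995) were also called higher as lists, each with adjusted p = 0.65 with an estimated correlation. NF-kB was not called without HPg PMA library 1 (0.723) or KO PMA library 3 (0.245), nor heat shock genes without HPg library 1 (0.566) or KO library 3 (0.0916), or in the blocked fit corrected for GC content, length and gene span (0.168).

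The histone list was called higher in the interaction (50 of 54 above 0, median 0.34, adjusted p = 4.05e-10), and that of genes with very long introns lower (0 of 20 above 0, median -0.50, adjusted p = 3.39e-07), each with adjusted p = 0.65 with an estimated correlation, and the long-intron call ended in the blocked fit corrected for GC content, length and gene span (0.44). The Zfp list was called lower (median -0.14, adjusted p = 5.89e-06, and adjusted p = 0.468 with an estimated correlation), which ended with the correction for GC content and length (0.0707). Across 10615 genes the interaction correlated with GC content (rho = 0.694, with -0.478 for PMA in HPg, 0.063 for PMA in KO and 0.391 for the lines with PMA) and with gene span (rho = -0.576), and after the correction for GC content and length with the block the latter was still -0.352. Ribosomal proteins (adjusted p = 0.0157, and adjusted p = 0.988 with an estimated correlation) were called higher as a list. They were not called without HPg library 3 (0.296), HPg PMA library 2 (0.791) or KO PMA library 1 (0.139) or 3 (0.252), nor with the correction for GC content and length (0.0827, and 0.341 with gene span and the block), and turned downward without HPg library 1 (0.174) or KO library 2 (0.0874). Olfactory and vomeronasal receptors (9 members, adjusted p = 0.0157, adjusted p = 0.391 with an estimated correlation and 0.0671 in the blocked fit) were called lower, and each of the 12 fits that left out 1 library ended this call (0.0578 to 0.531), as did leaving out the libraries numbered 2 (0.0938) and the correction for GC content and length (0.153, and 0.168 with gene span and the block). Of these lists edgeR called no member, also adjusted over the list alone, apart from Fosl1. Of the 22 other lists, with adjusted p from 0.066 to 0.999, cell cycle inhibitors and p53 targets passed in the blocked fit (adjusted p = 0.0293, and adjusted p = 0.652 there with an estimated correlation).

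**Figure D4:**
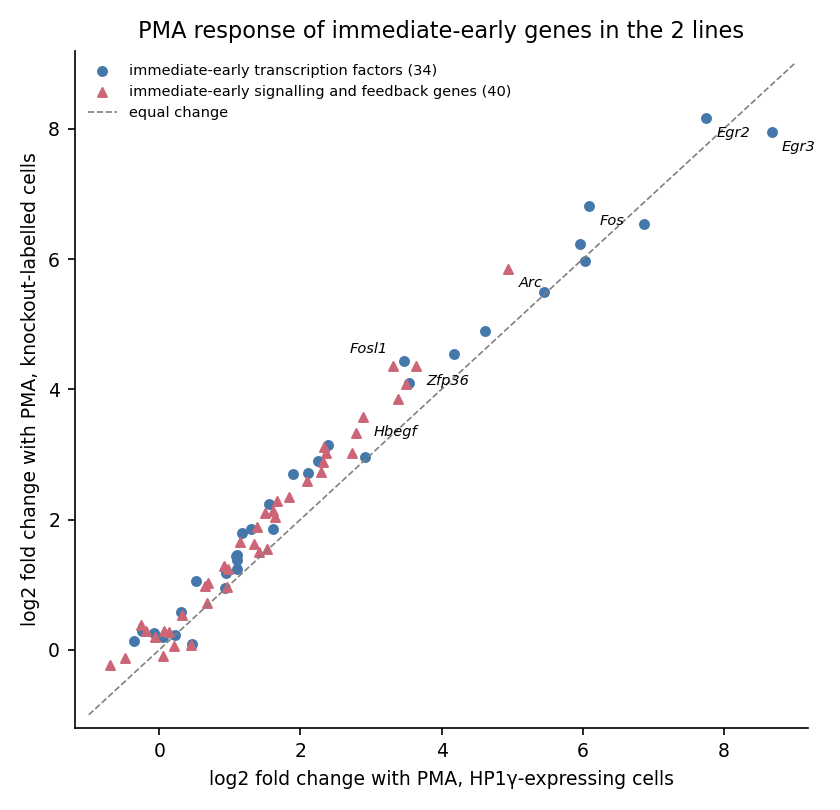
Log2 fold change with PMA in HPg cells (x axis) and in knockout-labelled cells (y axis), with 1 point per member of the 2 immediate-early lists (34 transcription factors, 40 signalling and feedback genes) and a dashed line of equal change. Of the points, 30 of 34 and 36 of 40 lie above the line, Fosl1 at 3.47 and 4.44 among them.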

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

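The tests of GC content and length and of HPg library 2 were chosen after the result was seen, and the gene span test and the label splits with the mean line difference removed were chosen after the pattern, and for the splits also the result without that removal, was seen but before their own results.

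The PMA response differed between the lines in 9 lists by the interaction test of camera with its preset correlation, and all 9 calls end with an estimated correlation, with adjusted p = 0.245 to adjusted p = 0.988. Immediate-early signalling and feedback genes (adjusted p = 2.04e-11, and 0.245 estimated) and immediate-early transcription factors (adjusted p = 1.22e-09, and 0.391) were called further up as lists in knockout-labelled cells. NF-kB targets (0.00875, with 0.65 estimated, 0.723 without HPg PMA library 1 and 0.245 without KO PMA library 3) and heat shock genes (0.00995, with 0.65 estimated, 0.566 without HPg library 1, 0.0916 without KO library 3 and 0.168 in the blocked fit corrected for GC content, length and gene span) did so too. The histone list was called higher (4.05e-10, and 0.65 estimated), and the lists of genes with very long introns (3.39e-07, with 0.65 estimated and 0.44 with that correction) and of Zfp genes (5.89e-06, with 0.468 estimated and 0.0707 corrected for GC content and length) lower, while edgeR called none of their members. The ribosomal protein list was called higher with no member called (0.0157), with 0.988 estimated, 0.341 with GC content, length and gene span corrected, 0.296 without HPg library 3, 0.791 without HPg PMA library 2, 0.139 and 0.252 without KO PMA library 1 or 3, and a downward direction without HPg library 1 (0.174) or KO library 2 (0.0874). The olfactory and vomeronasal receptor list was called lower (0.0157, with 0.391 estimated and 0.168 so corrected), a call that each of 12 left-out libraries ended (0.0578 to 0.531).

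The larger response of the immediate-early lists was seen in each replicate number, with median differences of 0.586, 0.229 and 0.449 for immediate-early signalling and feedback genes such as Hbegf and Trib1 (0.516, 0.171 and 0.405 after correction for GC content and length), and 0.548, 0.138 and 0.406 for transcription factors such as Fosl1 and Myc (0.397, 0.074 and 0.366). For signalling genes, a trend with GC content and length as the whole cause is argued against. After its removal in the blocked fit adjusted p was 1.21e-19, and 0.0147 with an estimated correlation (median 0.349, against 0.451 in the edgeR test). Gene span as the whole cause is argued against for this list too, although it still went with the corrected interaction (rho = -0.352). Its removal as well gave 1.92e-18, and 0.00731 with an estimated correlation (median 0.304, replicate medians of 0.121 to 0.378). For transcription factors both trends stay open. Their adjusted p was 2.34e-10 and 2.98e-08 with the preset correlation, but 0.0919 and 0.0772 with an estimated one, which ends the call. Their median fell from 0.341 to 0.204 and 0.158, with replicate medians of 0.048 to 0.340 after the last removal. HPg library 2 as the whole cause is argued against for both lists, with 8.53e-17 and 1.51e-11 in the blocked fit without it, at the preset correlation. With each gene's mean line difference removed, splits of the genotype labels gave a median difference as large for signalling genes in 4 of 200 (real 0.399, highest other 0.503). Among the 32 that part every same-number pair it was 1, the real split (highest other 0.356). That is the smallest share 32 splits can give. As this list had the smallest adjusted p of the 31 tested, chance is not excluded for it. Nor is it for transcription factors, with 32 of 200 (real 0.350, highest other 0.668) and 2 of 32 (highest other 0.387). The splits used values not corrected for GC content, length or gene span. That HP1γ restrains the immediate-early response to PMA is a hypothesis that these data do not test. The Cbx3 counts do not check the loss of HP1γ. The hypothesis stays open beside chance, for both lists, and a difference between these 2 lines unrelated to HP1γ. For transcription factors it stays open beside both trends too.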

How the results depend on the processing

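The corrections for GC content, length and gene span, the removal of chromosome medians, the fits without the libraries numbered 2 and the block without HPg library 2 were added after seeing the data, and the cause of the changes below was not tested. Counts of called genes are given in the order line untreated, line with PMA, PMA in HPg, PMA in KO, against 219, 411, 574 and 739. DESeq2 called 775, 1184, 1212 and 1279, and 1 in the interaction (Fosl1). The replicate block gave 2083, 3090, 2462 and 2221, with the GC and length correction 2919, 3485, 2236 and 2938, with gene span corrected as well 3213, 3721, 2525 and 2817, with chromosome medians removed 1164, 2059, 2483 and 2300, and without HPg library 2 1804, 3276, 1124 and 2491, with 1 in the interaction (Fosl1). Without the block, the GC and length correction gave 423 and 626, removal of chromosome medians 143 and 210, and leaving out the libraries numbered 2 592 and 1359 for the comparisons of lines, with PMA counts within 1.5 times. Fits of only the groups compared called 12 untreated and 222 for PMA in HPg. An adjusted p below 0.01 left 45, 69, 179 and 261, and at least a 2-fold change 135, 191, 256 and 369.

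Without 1 library the counts ranged from 46 to 329, from 60 to 573, from 244 to 332, from 295 to 604, and from 0 to 1 in the interaction. The correlation of the line difference without and with PMA ranged from 0.521 to 0.615 and that of the PMA response from 0.540 to 0.637. They were 0.773 and 0.823 with at least 1 CPM, 0.656 and 0.672 with the GC and length correction, 0.666 and 0.673 with gene span and the block as well, and 0.587 and 0.558 with the block without HPg library 2. The line difference had 0.658 with the block and the GC and length correction, and the PMA response 0.604 with limma-voom and 0.539 without the libraries numbered 2. Directions reversed for Cbx3 untreated with chromosome medians removed (0.080, and 0.082 with the block) and for the uncalled Ccn2: HPg_PMA vs HPg, where the log2 fold change went from -0.036 without HPg PMA library 2 to 0.757 without HPg library 2. They reversed for the histone list untreated without KO library 2 (adjusted p from 2.08e-07 to 0.885 over left-out libraries), for ribosomal proteins with PMA in KO without KO library 2 (1.33e-05 to 0.788), and in the interaction without HPg library 1 (0.174) or KO library 2 (0.0874; 1.18e-15 to 0.791 overall), each uncalled where reversed. The block ended no call of a gene named or counted in the report and changed no other call of a list than those given beside the results. Over the named genes and the lists, 9806 values kept direction and side of the threshold, 1207 became called and 920 lost the call, all with the same direction. With an estimated correlation 7 of 50 list calls stayed, all of PMA in 1 line. Other scaling factors moved the median of all genes by at most 0.1, except library size only for PMA in KO (-0.142). Depth was not varied, so how far it limited the calls was not tested.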

Other observations

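The edgeR, blocked, DESeq2 and limma-voom fits were planned. All other tests in this part but the splits that part every same-number pair were chosen after the result was seen, as were the genes of its first paragraph.

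Several strong changes lay in genes outside the lists. In both treatments the knockout-labelled line had more Chd3, a subunit of a nucleosome remodelling complex (reported above), and Emilin2, a matrix glycoprotein (1.34, adjusted p = 0.000324 by edgeR without PMA, and higher with it, adjusted p = 9.84e-05). That line also had less Olfm1 without PMA (-1.58, SE 0.13) and with it (-1.49, SE 0.125). Daam2, a formin of Wnt signalling, was lower in both treatments as well (-0.96, SE 0.11, and -1.15, SE 0.11). Hey1, a Notch target, was lower without PMA (-1.58, SE 0.20). PMA raised Ifrd1 (2.10 in HPg and 2.59 in knockout-labelled cells), the cyclin Ccnl1 (1.81 and 1.77), Arrdc3 (1.60 and 1.57), Gprc5a (2.11 and 2.53), Insig1, a regulator of sterol synthesis (1.67 and 1.87), and Gch1, the first enzyme of tetrahydrobiopterin synthesis (2.23 and 2.85). Cbx2, a Polycomb subunit, fell by 1.08 and 1.00, and Skida1 had -0.80 and -0.69.

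The chromosome medians of the line differences had an SD of 0.143 without and 0.138 with PMA, above the highest of 1000 shuffles of 10608 genes (0.020 and 0.024). That of PMA in HPg cells was 0.052 (highest shuffle 0.024, and 0.023 against 0.019 after GC and length correction), and that of PMA in knockout-labelled cells 0.019 (highest 0.022, and 0.022 against 0.020 corrected). A GC and length trend is argued against, as the SD was 0.140 after its removal. Local groups of neighbouring genes as the whole cause are argued against on the 10 chromosomes beyond the shuffles, the only ones tested. There 91.7% of windows of 50 genes (100 of 109) had the sign of their chromosome, except on chromosome 7 (6 of 15), where local groups stay open. These chromosomes were chosen by the same medians, which favours the shared sign. Pairs of neighbouring genes called in the same direction were more frequent than in shuffles within chromosomes. In the blocked fit 340 neighbouring pairs were called in the same direction without PMA and 616 with it. Shuffles within chromosomes gave at most 288 and 503. That fit was not corrected for GC content, length or gene span, and the strand setting is not given. Whether local groups lie behind these pairs was therefore not settled. A difference in copy number between the lines is a hypothesis that the values go with, as chromosome medians without and with PMA correlated at 0.919, and no DNA was measured to test it. The splits are too few for a share under 0.05: 1 of 10 gave an SD as large in each treatment, with 0.142 against a highest other of 0.078, and 0.138 against 0.068. An effect of HP1γ on whole chromosomes is confounded with the lines, since each genotype is 1 line.

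HPg library 2 detected 17822 genes and had 618 genes at a count of 1, against 1209 to 1547 in the others. Lower depth is argued against, since KO library 1, with the lowest total, detected 2614 more genes. Among genes with 20 to 39 counts 62.6% (SE 1.55) had an even count, against at most 54.3% in the others. Fewer distinct fragments behind the counts stay open as a cause, but need not favour even counts. Whether reads or fragments were counted is not given, and the source of the excess was not settled. No biological explanation was tested.

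For the number of called genes 1 of 10 splits of the libraries, the real one, gave as many in each of the 4 comparisons of 2 groups (219, 411, 574 and 739, highest other 0), and these splits are too few for a share under 0.05. For the interaction, where edgeR called 0 genes (328 at unadjusted p below 0.05, DESeq2 1, limma-voom 0), all 100 splits drawn gave as many, as any count does against 0, so this test says nothing. The highest other gave 1110 in a split that exchanges the PMA labels of 4 of the 6 KO libraries and keeps those of HPg, so that its contrast contains the PMA response itself. Splits of the genotype labels in each treatment likewise put the line difference into the interaction, so without its removal they decide nothing for the immediate-early lists. Without removal 17 of 200 gave a median as large for signalling genes (real 0.399, highest other 0.554) and 51 of 200 for transcription factors (real 0.350, highest other 0.724), and 5 (highest other 0.506) and 8 (highest other 0.574) of the 32 that part every same-number pair. In the blocked fit 340 pairs of neighbouring genes were called in the same direction without PMA, against 242.1 on average and at most 288 in shuffles within chromosomes, and 616 with PMA, against 455 and at most 503.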
